A study of Mus musculus with 6 samples.

How the data were processed

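RNA was taken from 6 mouse retinas, 1 retina per library, 3 labelled Samd7 KO and 3 labelled wild type. Per the labels' protocols, polyadenylated RNA was made into cDNA with a low-input template-switching kit, sheared, ligated to adapters and amplified for 15 cycles. No molecular identifiers are described, so that amplified copies of a molecule cannot be separated. The interval of a read ratio covers counting error only, while the 95% intervals of log2 fold changes come from limma and the spread between libraries. Per the submitters' processing notes, the tools were DRAGEN, cutadapt 3.0, STAR 2.7.3a, HTSeq 0.12.4, SAMtools 1.9 and DESeq2, with the builds GRCm38 and mm10; their roles and the strand setting are not given in the sources used here.

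The authors' deposited table holds 49997 genes. Its per-library signal is the authors' gene read count divided by 1 size factor per library, per the file headers and the values. It also holds the authors' log2 fold change and its standard error, a Wald score against a log2 fold change of 0 and of 1, and the p-value and adjusted p-value of each test, all deposited by the authors from DESeq2 per the file headers. Each library's values were divided by the worth of 1 read. All 166478 values above 0 came out whole within 0.01 reads (100%), with a largest distance of 2.49e-04 reads, and 16670 genes had 0 in all libraries. All 49997 symbols matched the NCBI RefSeq gene table of the GRCm38.p6 assembly, the build named by the submitters, from which gene positions were taken.

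Because the values were normalized rather than raw counts, the main test was limma-trend on log2(value + 1), as fixed beforehand for that unit, and count tests on the recovered reads became alternatives. Genes with a value of at least 10 in at least 3 libraries were kept, 20277 in all. Fold changes in the text are ratios of group means of normalized reads, and log2 fold changes, with their standard errors, are on the log2(value + 1) scale, which understates changes of low genes. P-values are two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Gene lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, with a correlation estimated per list, and with fry. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

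The groups, the 25 gene lists, the test, the other ways to run it and the rule for named genes were set before the data were examined. The rule named Samd7 and all opsins. It also named the 10 largest rises and falls among called genes that changed at least 2-fold, with a mean of at least 1 CPM, groups that did not overlap and a symbol that is not a predicted model. From each list it named up to 4 members with the smallest adjusted p. The values of 2 single genes are not reported here. Genes outside it are said to be chosen after their values were seen. Besides those identified in the results, these were Gm33590, Nr2e3, Edn2, Lcn2 and Serpinf1. Set beforehand as other ways to run the test were edgeR with RLE and upper-quartile factors, DESeq2, limma-voom with sample quality weights, other filters and pseudocounts, a stricter threshold, a replicate block and leaving out each library. The count test named beforehand was edgeR with TMM factors, run here with the filter of the main test. Added after seeing the data were scaling to total reads and removal of each library's trend with transcript length. Length was taken from the longest GENCODE transcript of a symbol. Replicates differed by 6.80 to 33.1 times the counting noise (chi-square per degree of freedom), so that none was a second sequencing of the same library; separate preparations from 1 retina would also differ by more than counting noise.

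The tests were run on simulated counts of the 20277 genes for this comparison, drawn from the real means, spreads and library sizes with 200 genes changed. With limma-trend, 59.7% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, and 9.30% of calls were false, more than the 5% nominal rate. The simulated false share was 8.67% with edgeR, 8.33% with limma-voom and 13.0% with DESeq2. All these rates come from a single draw with 200 changed genes. The real comparison called 2432, so the rates need not carry over to it. The changed list was called and 0 of the unchanged lists were. Genes were drawn independently of each other, so this run cannot show how often lists of genes that vary together are called falsely.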

Results

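Gene expression was measured by sequencing of polyadenylated RNA in 6 mouse retinas, 1 retina per library. The 3 libraries labelled Samd7 KO were compared with the 3 labelled wild type. The KO retinas were taken at postnatal day 31 and the wild-type retinas at postnatal day 36, so that age and genotype were not separable. Anything else that may have differed between the groups, such as the handling of the retinas, was not separable either. All 6 retinas carried a male label. The question named by the study is whether Samd7, a sterile alpha motif protein of photoreceptors, keeps the identity of photoreceptor types and restricts each to a single light receptor. The values are gene read counts divided by 1 size factor per library. The reads recovered from them summed to 44.2, 48.6 and 53.1 M in the libraries labelled Samd7 KO 1, 2 and 3, and to 62.8, 47.7 and 55.4 M in wild type 1, 2 and 3.

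Samd7 itself (chromosome 3, 30746293 to 30767174, GRCm38) was higher in the libraries labelled Samd7 KO. Its normalized read count was 49508 ± 7225 (SD, n = 3) in those libraries and 7537 ± 1029 (SD, n = 3) in wild type, 6.57-fold higher (log2 fold change 2.72, SE 0.11, limma adjusted p = 1.54e-08). All 3 libraries labelled KO, at 57837, 45755 and 44932, lay above the wild-type libraries, at 6349, 8141 and 8122. The targeted gene was therefore not lower under the KO label, and directions below are given for the retinas labelled Samd7 KO. A count over the whole gene does not show an altered allele that is still transcribed, and the labels do not say which part of the gene was changed. The noncoding gene Gm33590, which lies inside Samd7 (chromosome 3, 30752309 to 30756744), was 19.1-fold higher, at 454 ± 29.9 against 23.8 ± 3.42 normalized reads (SD, n = 3 each, limma adjusted p = 1.57e-08). Whether the counting used strand is not given in the sources used here, so reads of these overlapping genes were not separated.

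The cone opsins moved in opposite directions in the retinas labelled Samd7 KO. Opn1sw, the short-wavelength cone opsin (chromosome 6, 29376671 to 29380513), rose 9.53-fold, from 43705 ± 1291 to 416374 ± 17337 normalized reads (SD, n = 3 each, log2 fold change 3.25, SE 0.06, limma adjusted p = 8.27e-12). Opn1mw, the middle-wavelength cone opsin (chromosome X, 74127466 to 74150756), was 2.47-fold lower, at 9619 ± 297 against 23757 ± 877 (log2 fold change -1.30, SE 0.06, limma adjusted p = 5.64e-08). Opn1sw took 0.795% to 0.850% of the reads in the libraries labelled KO and 0.0817% to 0.0851% in wild type. Rgr, an opsin of the pigment epithelium and Müller glia, was 4.23-fold lower (limma adjusted p = 3.75e-04). Opn3 (log2 fold change -0.56, SE 0.20, limma adjusted p = 0.0996), Opn4 (log2 fold change -0.07, SE 0.11, limma adjusted p = 0.759) and Rrh (log2 fold change -0.15, SE 0.09, limma adjusted p = 0.355) did not pass the test. Opn5 had 2 reads in the libraries labelled KO and 3 in wild type, a ratio of 0.728 with a counting interval of 0.0608 to 6.35, so that a difference was not detectable at this depth. Of 7 opsins tested, 1 rose and 3 fell, or 1 and 4 adjusted over the list alone, and camera placed the list lower (adjusted p = 0.0193, and adjusted p = 0.233 with an estimated correlation; over 18 refits of the list test the adjusted p ranged from 0.00621 to 0.0554).

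**Figure D1:**
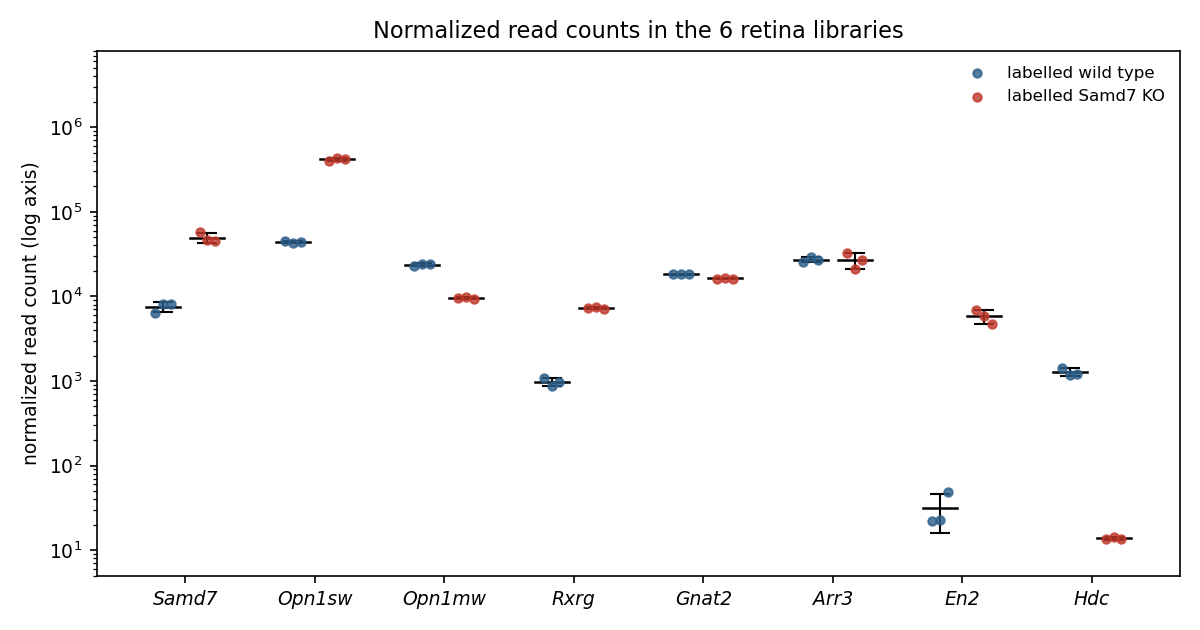
Normalized read counts (vertical log axis) of 8 genes in each library, wild type in blue and labelled Samd7 KO in red; points are libraries, long bars are means and capped bars are 1 SD (n = 3 per group). Samd7 and Opn1sw sit higher in all libraries labelled KO, Opn1mw lower, while the groups overlap for Arr3.

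Cone genes split into a set that rose and a set that did not. Of 16 tested, 7 rose, 1 fell and 8 did not pass, or 10 and 2 adjusted over the list alone. The risers were Opn1sw, Ccdc136 (7.63-fold, from 10982 ± 649 to 83819 ± 3820), the transducin subunits Gngt2 (9.12-fold) and Gnb3 (4.24-fold), the retinoid receptor Rxrg (7.50-fold), and the cone cyclic nucleotide-gated channel subunits Cnga3 (9.24-fold) and Cngb3 (7.46-fold). Their log2 fold changes lay between 2.07 and 3.25, and Opn1mw was the member that fell. Cone arrestin Arr3 had 26646 ± 5511 normalized reads in the libraries labelled KO and 27128 ± 1955 in wild type (SD, n = 3 each, log2 fold change -0.04, 95% interval -0.31 to 0.22), a sign that turned with total-count scaling. The log2 fold changes of Gnat2 (-0.17, 95% interval -0.30 to -0.04, limma adjusted p = 0.0866), Pde6h (-0.06, -0.20 to 0.08) and Pde6c (0.27, 0.08 to 0.45, limma adjusted p = 0.0673) also did not pass. The list stood higher than other genes by camera (adjusted p = 3.82e-09, and adjusted p = 0.0527 with an estimated correlation). Arr3, Gnat2, Pde6h, Pde6c, Gnb3, Cnga3 and Cngb3 were picked for mention after their values were seen.

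Rod genes were lower as a group. Of 15 tested, 12 fell, 0 rose and 3 did not pass, or 14 fell adjusted over the list alone. Gnat1, the rod transducin alpha subunit, was 1.80-fold lower (796016 ± 33658 against 1435230 ± 93969 normalized reads, SD, n = 3 each, limma adjusted p = 1.62e-06). The rod channel subunit Cngb1 was 1.99-fold lower, Gnb1 1.77-fold lower, and Nrl, the transcription factor that sets rod identity, 1.62-fold lower (limma adjusted p = 9.66e-06). Nr2e3, the rod factor that represses cone genes, did not pass (log2 fold change -0.12, 95% interval -0.26 to 0.02, limma adjusted p = 0.244). Camera placed the list lower (adjusted p = 1.80e-17, and adjusted p = 0.0527 with an estimated correlation). Genes used by rods and cones alike moved in both directions. Of 25 tested, 3 rose, 9 fell and 13 did not pass, or 5 and 10 adjusted over the list alone, with Guca1b 2.05-fold lower, Prph2 1.54-fold lower and Rpgrip1 1.49-fold higher (camera adjusted p = 4.03e-04, and adjusted p = 0.311 with an estimated correlation). Arrestin Sag, picked after its value was seen, had a log2 fold change of 0.19 (95% interval 0.06 to 0.31, limma adjusted p = 0.0575).

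**Figure D2:**
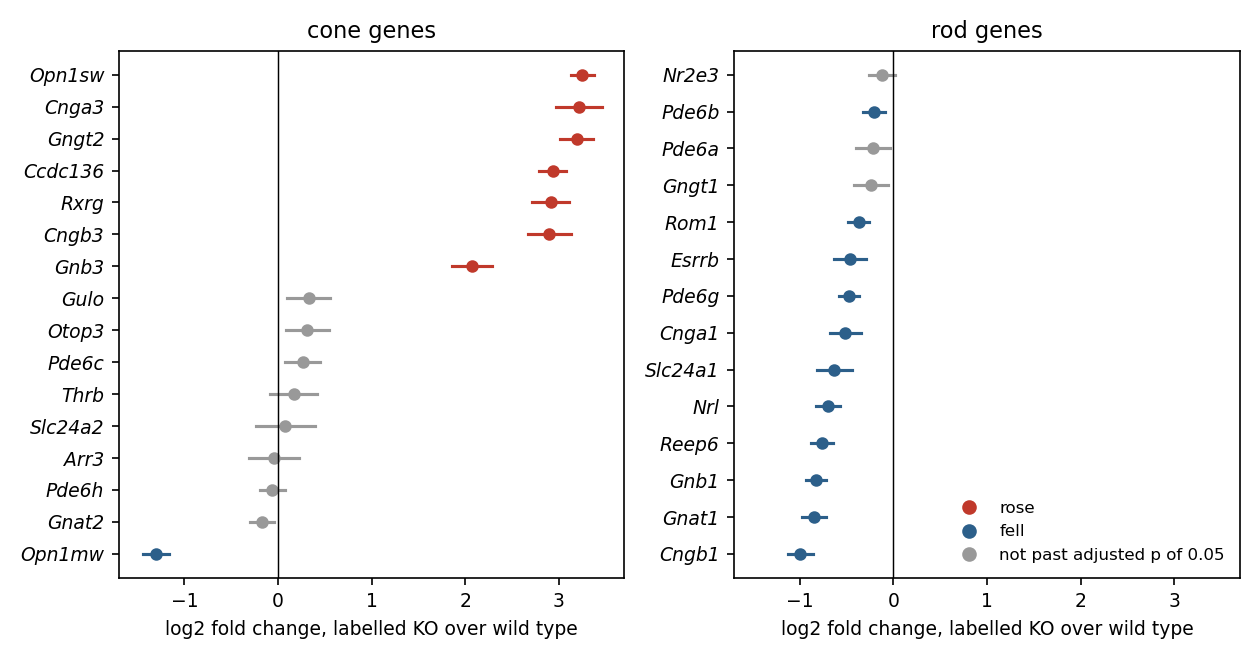
Log2 fold changes of cone genes (left) and rod genes (right), retinas labelled Samd7 KO over wild type, with 95% intervals from limma (n = 3 per group); red rose, blue fell, grey did not pass an adjusted p of 0.05. The 7 cone genes that rose lie between 2.07 and 3.25, apart from the other cone genes.

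Among photoreceptor transcription factors, 4 of 23 rose, 3 fell and 16 did not pass, or 5 and 4 adjusted over the list alone. Rxrg and Prdm1 rose (log2 fold changes 2.91 and 0.92), and Mef2c was 4.78-fold lower (1055 ± 97.6 against 5047 ± 155 normalized reads, SD, n = 3 each, limma adjusted p = 9.09e-09). The list as a whole did not shift (camera adjusted p = 0.895). Photoreceptor synapse genes did not shift either (adjusted p = 0.686), with 3 of 19 higher and 2 lower, or 5 and 2 adjusted over the list alone. Among them were Cabp4, 1.45-fold lower, and Lrit1, 1.46-fold higher.

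Transcripts of Polycomb repressive complex members, the silencing complexes to which Samd7 belongs, were nearly level between groups. Of 32 tested, 2 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.895). Samd11, the closest relative of Samd7 in photoreceptors, had 35091 ± 4463 against 20247 ± 6292 normalized reads (1.73-fold, limma adjusted p = 0.00643), a call that ended with edgeR on recovered reads (adjusted p = 0.0668 with RLE, 0.0902 with upper-quartile and 0.0728 with TMM factors, range over all alternatives 1.96e-05 to 0.0902). Of 39 Hox genes, classical Polycomb targets, 0 reached the level needed for a test. Of 50 developmental transcription factors known as Polycomb targets, 10 were tested, 1 rose and 0 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.895). The riser was En2, a homeobox factor of the midbrain and hindbrain.

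En2 (chromosome 5, 28165696 to 28172190) was also first among the single genes chosen by the size of their rise, 185-fold higher (5801 ± 1110 against 31.3 ± 15.3 normalized reads, SD, n = 3 each, log2 fold change 7.57, SE 0.26, limma adjusted p = 2.91e-09). It was followed by Fabp7, a brain fatty acid binding protein (137-fold, 8706 ± 832 against 63.5 ± 3.08), Insm2, a zinc finger factor (130-fold, 7077 ± 272 against 54.3 ± 16.9), Bpifb6 (49.2-fold) and Crp, C-reactive protein (47.6-fold). Tal2, Tekt4, Myocd, the T-type calcium channel subunit Cacna1h and the noradrenaline transporter Slc6a2 completed the 10 and rose 33.3-, 29.4-, 25.9-, 15.5- and 12.6-fold. Without wild type 3 the rises of Tal2 and Slc6a2 were 52.8- and 19.4-fold, and without wild type 1 they were 23.4- and 9.26-fold. Hdc, the enzyme that makes histamine (chromosome 2, 126593659 to 126624025), had the largest fall of the genes eligible under that rule, 92.6-fold lower at 13.8 ± 0.583 against 1282 ± 139 (limma adjusted p = 1.42e-10). Bst1, Sh2d1a, Tcp11, Mef2c, Slc6a20a, Gchfr, Dock8, Zan and Rpe65 were 7.58-, 5.64-, 5.41-, 4.78-, 5.08-, 4.67-, 4.52-, 4.41- and 3.94-fold lower. The Rpe65 call ended with edgeR and TMM factors (adjusted p = 0.0504, range over all alternatives 2.12e-04 to 0.0504). The Rpe65 fall was 6.59-fold without KO 3 and 3.10-fold without KO 2.

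**Figure D3:**
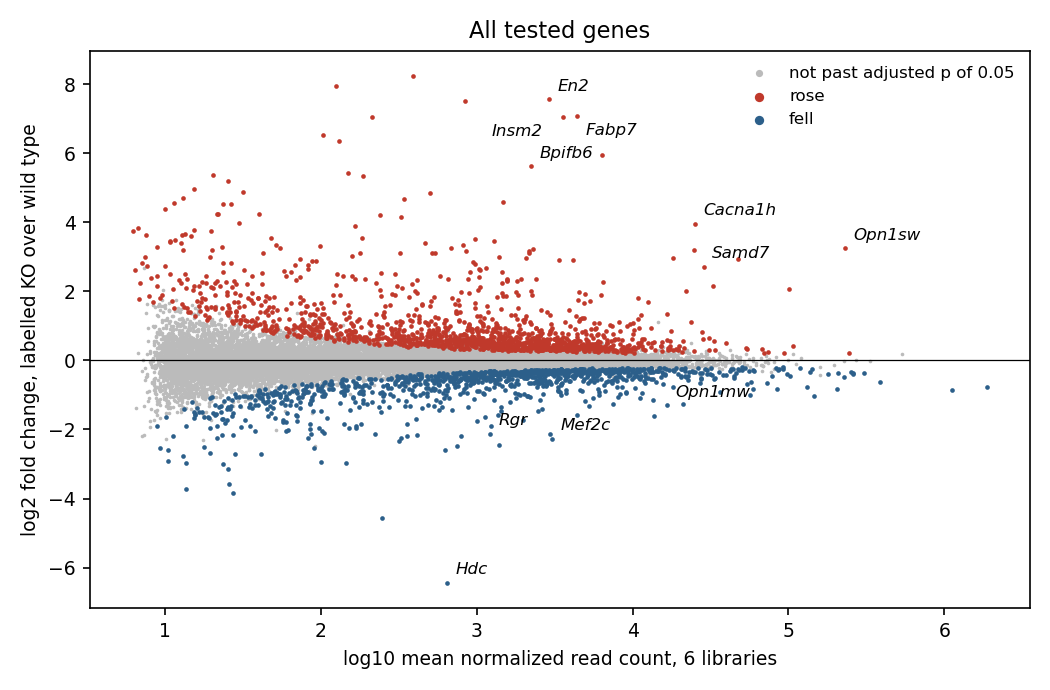
Log2 fold change of the 20277 tested genes, retinas labelled Samd7 KO over wild type, against the log10 mean normalized read count of the 6 libraries; red rose, blue fell, grey did not pass a limma adjusted p of 0.05. Opn1sw, Samd7 and Cacna1h stand above most genes of similar level, and Hdc far below.

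Across the transcriptome 2432 of 20277 tested genes changed, 1376 higher and 1056 lower in the retinas labelled Samd7 KO (56.6% higher), and 655 of them changed at least 2-fold, 432 higher and 223 lower. Large changes were mostly increases: 71 genes rose and 7 fell at least 8-fold. Of the called genes, 2415 had groups that did not overlap; 31.1% of all tested genes had this order, against 10% by chance. The count fell to 1497 without Samd7 KO 3, 1470 without wild type 2 and 1313 without wild type 3. Scaling to total reads, chosen after seeing the data, gave 2810 genes, 71.2% of them higher, while edgeR with upper-quartile factors gave 2626 genes with 48.6% higher, so that the majority direction depended on scaling. Limma-voom with sample quality weights gave 4650 genes. The authors' deposited table, from DESeq2, listed 2788 genes at an adjusted p under 0.05 against no change, 1614 higher and 1174 lower, and 195 against a log2 fold change of 1. Of the 2432 genes called here, 2316 were also called in the authors' deposited table, 0 of them with the opposite sign. Both sets of calls come from the same libraries, so this overlap is no separate support.

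Genes of reactive gliosis and retinal stress rose together. Of 20 tested, 14 rose, 1 fell and 5 did not pass, or 16 and 1 adjusted over the list alone, with a median log2 fold change of 1.08. Fgf2, a survival factor induced in stressed photoreceptors, rose 6.94-fold (from 246 ± 43.9 to 1709 ± 250 normalized reads, SD, n = 3 each, limma adjusted p = 1.33e-07). Edn2, endothelin 2, rose 6.10-fold, complement C4b 5.08-fold, and Gfap, the intermediate filament of reactive glia, 3.72-fold. Lcn2 was 1.86-fold lower. Camera placed the list higher (adjusted p = 1.61e-15, and adjusted p = 0.0527 with an estimated correlation). Müller glia markers did not shift in 1 direction as a list (camera adjusted p = 0.429). Of 14, 5 rose and 2 fell, or 7 and 3 adjusted over the list alone, with Crym 1.76-fold higher and Glul 1.44-fold lower.

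Microglia and macrophage markers rose in 11 of 16 cases with 0 lower, or 15 and 1 adjusted over the list alone. Cx3cr1 rose 2.24-fold, Ctss 1.85-fold and C1qb 1.43-fold, and camera placed the list higher (adjusted p = 4.65e-08, and adjusted p = 0.117 with an estimated correlation). Red blood cell markers rose in all 5 tested, and in 5 adjusted over the list alone. Hbb-bs rose 3.96-fold, from 723 ± 144 to 2865 ± 497 normalized reads (camera adjusted p = 1.66e-08, and adjusted p = 0.161 with an estimated correlation); the alpha and beta globin copies are near-identical, and reads could be split between them. Among endothelial and pericyte markers 2 of 14 rose and 0 fell, or 4 and 0 adjusted over the list alone, with Kdr 1.79-fold higher (camera adjusted p = 0.0401, over 18 refits 0.00925 to 0.192, and adjusted p = 0.660 with an estimated correlation). Among astrocyte markers 2 of 6 rose and 0 fell, or 3 and 0 adjusted over the list alone, Gfap among them (camera adjusted p = 0.0370, over 18 refits 0.00659 to 0.0848, and adjusted p = 0.415 with an estimated correlation).

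Markers of the retinal pigment epithelium, the tissue that adjoins the retina, moved the other way. Of 15 tested, 10 fell, 1 rose and 4 did not pass, or 11 and 1 adjusted over the list alone, with a median log2 fold change of -1.14. Ttr was 3.22-fold lower (472 ± 221 against 1522 ± 410 normalized reads, SD, n = 3 each, limma adjusted p = 0.00205), Rdh5 2.50-fold lower and Rgr 4.23-fold lower, while Serpinf1 was 1.34-fold higher, a call that ended with upper-quartile factors, without a filter, with a replicate block and with any library but KO 2 left out. Camera placed the list lower (adjusted p = 2.82e-06, and adjusted p = 0.128 with an estimated correlation). Lens markers had 6 tested members, of which 0 rose and 0 fell by limma and likewise adjusted over the list alone; the library labelled wild type 3 stood apart, with 219 normalized reads of Crybb1 against 17.3 to 33.6 in the other libraries (camera adjusted p = 0.116, and lower in 5 of 18 refits).

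Markers of the other retinal neurons did not shift. Bipolar cell markers had 0 of 20 higher and 3 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.994), and horizontal cell markers had 0 of 9 changed, also adjusted over the list alone (adjusted p = 0.972). Amacrine markers had 1 of 16 lower, Th, at 1.48-fold lower (the same adjusted over the list alone, adjusted p = 0.771). Ganglion cell markers had 1 of 14 higher, Nefh, at 1.29-fold (the same adjusted over the list alone, adjusted p = 0.994), a call that ended without wild type 2. Immediate early genes had 1 of 15 higher, Jun, and 2 lower (2 and 5 adjusted over the list alone, adjusted p = 0.409). Circadian clock genes had 0 of 16 higher and 3 lower, with Ciart 1.43-fold lower (0 and 3 adjusted over the list alone, adjusted p = 0.278), and cell cycle genes had 1 of 11 higher, Plk1, and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.262, but fry adjusted p = 0.0123). Mitochondrially encoded genes had 0 of 13 higher and 4 lower (0 and 7 adjusted over the list alone), with COX1 1.31-fold lower. Camera placed that list lower (adjusted p = 4.65e-04, and adjusted p = 0.660 with an estimated correlation), while fry did not call it (fry adjusted p = 0.377). The share of mitochondrial reads overlapped between groups, 0.899% to 1.18% in the libraries labelled KO and 0.972% to 1.37% in wild type. The COX1 call itself ended with a replicate block and without KO 2, KO 3, wild type 2 or wild type 3.

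**Figure D4:**
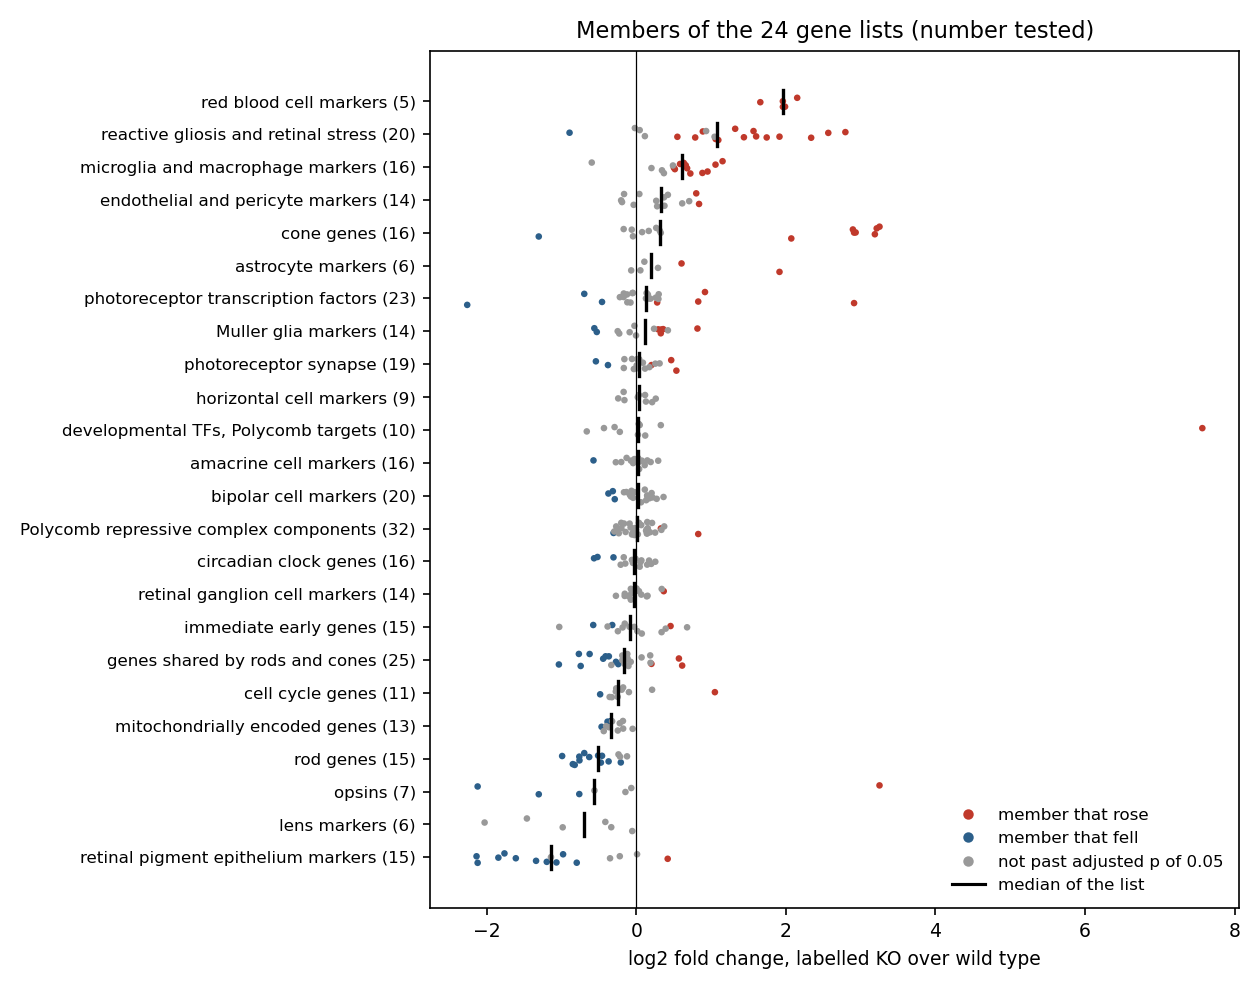
Log2 fold changes of the members of the 24 tested gene lists, retinas labelled Samd7 KO over wild type, with the number of tested genes after each name; points are genes (red rose, blue fell, grey did not pass a limma adjusted p of 0.05) and black bars are list medians. Stress and red blood cell lists lie to the right, and pigment epithelium and rod lists to the left.

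Of 24 lists, camera with a preset correlation shifted 11, 6 higher and 5 lower, and 7 of them also moved by fry, which called 8 lists, cell cycle genes being the other. With a correlation estimated per list, camera called 0 lists after adjustment and 6 at an unadjusted p under 0.05. The labels do not say that the 3 retinas of a group came from separate mice, so p-values measure the spread between these retinas.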

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

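The alternatives set beforehand included edgeR with TMM factors. Scaling to total reads and removal of the transcript-length trend were chosen after seeing the data. The count of changed genes, 2432, moved by over 1.5 times to 4650 with limma-voom and sample quality weights and to 1189 at an adjusted p under 0.01, where the stricter threshold is the cause. Leaving out single libraries gave 1313 (without wild type 3) to 3247 (without KO 1) genes, with 1497 without KO 3 and 1470 without wild type 2. Why these counts and the limma-voom count moved was not tested. With scaling to total reads 71.2% of the called genes were higher, against 56.6%, and with upper-quartile factors 48.6% of 2626 genes, so that the majority turned to lower. The other settings gave 1624 to 2810 genes, and 0 shared calls changed sign under any setting. A shared call passes in both fits of the same or overlapping libraries, so a change of sign was hardly possible. Replicate block: the same-number libraries had deviations correlated at -0.30, -0.23 and -0.16, which gave no sign of pairing by number. Pairing is not excluded, because deviations also followed transcript length. The rank correlations with length were opposed in KO 1 (-0.50) and wild type 1 (0.31), and in KO 2 (0.44) and wild type 2 (-0.35). They were small in KO 3 (-0.0027) and wild type 3 (0.023). A replicate block gave 1624 genes and 12 lists. Of the 11 lists, 8 were called in 18 of 18 refits, the opsins in 15, astrocyte markers in 13 and endothelial markers in 12, and camera with an estimated correlation called 0. Only Opn4 and Arr3, which were not called, turned sign (log2 fold changes). Opn4 was 7.7e-04 with limma-voom and between -0.14 and 0.029 with single libraries left out; Arr3 was 0.013 with scaling to total reads, 0.021 with the length trend removed, 0.012 without wild type 2 and between -0.190 and 0.113 with single libraries left out. Of 103 called named genes, 83 were never lost. Many of these were named for a small adjusted p or a large change, so that share does not hold for all calls. Of all 2432 called genes, 53.4% were kept without wild type 3 and 91.0% without KO 1.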

Other observations

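Gene groups chosen after seeing the data add to the picture in the retinas labelled Samd7 KO. The whole-gene Samd7 count neither bears out nor refutes that label. All tests here were chosen after the result was seen, except the region test, the splits and the tests of lists set beforehand. Glycolysis enzymes and transporters fell in 14 of 19 cases with 0 higher (median log2 fold change -0.35, camera adjusted p = 3.48e-10 over 9 such lists, and adjusted p = 0.295 with an estimated correlation). These 9 lists were tested on the main values only, not with other scalings, left-out libraries or the transcript-length trend removed. Hk2, the hexokinase of photoreceptors, was 1.46-fold lower (limma adjusted p = 0.00146), Pgam1 1.42-fold lower and Gapdh 1.31-fold lower, and Slc16a8, a lactate carrier of the pigment epithelium, 3.64-fold lower. Rod genes, of cells rich in these enzymes, fell in 12 of 15 cases beside them (median log2 fold change -0.51), and pigment epithelium markers in 10 of 15.

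Interferon-stimulated genes rose in 11 of 17 cases with 0 lower (camera adjusted p = 7.64e-08, and adjusted p = 0.294 with an estimated correlation), with Ifit1 3.74-fold higher. Class I antigen presentation genes rose in 4 of 10, with H2-D1 2.30-fold higher, and reads can be shared with its close relatives (adjusted p = 9.67e-05, and adjusted p = 0.294 with an estimated correlation). Complement components rose in 8 of 14 and fell in 1, with Serping1 1.92-fold higher and Cd59a 1.70-fold lower (adjusted p = 2.19e-04, and adjusted p = 0.295 with an estimated correlation). Microglia and macrophage markers were also higher, in 11 of 16 cases. That list shares C1qa, C1qb and C1qc, which are made by microglia, with the complement list. All of them are among the complement risers, so the counts of these lists are not independent. The unfolded protein response had 6 of 17 higher, led by Hspa5 at 1.53-fold, and 2 lower, led by Trib3 at 1.96-fold (adjusted p = 0.190). Motile cilium genes did not shift (adjusted p = 0.560), with 2 of 17 higher, Dnaic1 at 10.9-fold and Tekt4 at 29.4-fold, and 1 lower, Dnaic2, at 1.92-fold; calcium channel subunits (adjusted p = 0.581), cholesterol synthesis enzymes (adjusted p = 0.560) and heat shock genes (adjusted p = 0.768) did not shift either. Of genes at least 2-fold above a floor of 3 reads over 1 group, 92 had 0 reads in wild type and 82 had 0 reads in the libraries labelled KO. Among the former Krt73 was at least 32.4-fold and Amdhd1 at least 28.0-fold higher, and among the latter Nms, a neuropeptide gene, was at least 6.72-fold lower. The lens genes Lim2, Crygf and Foxe3 were also among the latter, with 46 of 48, 25 of 25 and 17 of 17 reads in wild type 3, the library that stood apart for lens markers.

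The libraries also varied along transcript length within groups. Across 14108 genes, which are not independent replicates, the rank correlation of a library's deviation from its group mean with length was -0.50 in Samd7 KO 1 and 0.44 in KO 2, and 0.31 in wild type 1 and -0.35 in wild type 2. Between groups the rank correlation of log2 fold change with length was 0.30. With each library's trend removed, 2703 genes were called and 9 of 24 lists, and 2234 of the 2432 genes were kept.

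Samd7 reads were higher in the libraries labelled Samd7 KO. A change of the whole region is argued against: the 9 tested genes within 0.5 Mb, with Samd7 and Gm33590 inside it left out, had a median log2 fold change of 0.0661 and 0 of them passed, Sec62 and Phc3 included. An exchange of the labels of the groups stays open on these counts. All 3 libraries labelled KO exceeded every wild-type library, and whole-gene counts do not show the allele. Under an exchange, the 9.53-fold higher Opn1sw and the stress genes, 14 of 20 higher and 1 lower, would belong to the wild-type retinas. A feedback rise of transcripts from a mutated gene may also account for the higher Samd7 reads, and was not tested.

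Of 16 cone genes 7 rose, and of 15 rod genes 12 fell; both list calls were lost with an estimated correlation (adjusted p = 0.0527 for each). A larger share of cone cells as the whole cause is argued against by 9 of the 16 cone genes whose 95% interval lay wholly below a log2 fold change of 1. A smaller share of rod cells as the whole cause would lower all 15 rod genes alike, if only rods made them. The interval of 11 of the 15 excluded the list median, 6 below and 5 above it, which argues against that cause under this condition. Whether other cells also made some of these transcripts was not tested. Scaling of the libraries moved the median gene by at most 0.0583. A loss of repression of some cone genes within rods may account for the split, as may age, day 31 against day 36, and neither was tested.

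Pigment epithelium markers were lower. If less pigment epithelium had been left on the retina, the 15 markers would vary together within groups; their mean correlation was 0.0996, at the 94.0th percentile of 10000 random lists matched on expression, under the 95th percentile set for it and above the random median of -0.01. That mean joins opposed sets, picked after their values were seen: Rpe65, Rgr, Ttr, Rdh5 and Lrat were all low in KO 2 (log2 deviations -1.17 to -0.54) and high in KO 3 (0.37 to 1.18), while Dct, Mlana, Pmel, Slc45a2 and Tyrp1 were low in KO 3. Less adhering tissue therefore stays possible and cannot be told apart from a change in the tissue itself. As first written, any value under the 95th percentile was to argue against less adhering tissue; that bound was moved to the random median, and the verdict left open, after the value was seen.

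Of the 10 splits of the 6 libraries, too few for a share under 0.05, the real one gave 2432 genes and the highest other 0 (limma; 5379 and 2132 at an unadjusted p under 0.05). For genes changed at least 2-fold the values were 655 and 0, and for gene lists 11 and 8. In each case 1 of the 10 splits, the real one, gave a result as large. The split with 2132 genes set KO 1, wild type 2 and wild type 3 against the rest.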
